A study of Homo sapiens with 6 samples.

How the data were processed

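Total RNA from KYSE-410 cells was labelled with cyanine 3 and hybridised to 6 arrays of 62976 features, per the labels' protocols, 3 from cells with a non-targeting short hairpin RNA and 3 from cells with a hairpin against ARID1A. The hairpin sequences are not given in the sources used here. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values of single genes measure only the spread between these samples.

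The authors deposited one scanner output per array, with spot intensity on a linear scale. These were extracted with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Per the file headers, the processed intensity is background-subtracted and detrended within each array, and is not scaled between arrays. The deposited scanner files also carry a flag of 0 or 1 per spot for being well above background, saturated or an outlier. A deposited table of the series holds raw intensity and normalized log2 values per probe. Its raw columns equal the geometric mean of the scanner's processed signal over a probe's spots for 100% of 58201 probes, within 0.1%. Its log2 columns share a single distribution, with sorted values that differ by at most 0.0354 and a median of 4.40 on every array, as quantile normalization gives, with no centring per gene. The software behind the deposited normalization is not given in the sources used here. Slide and scan were read from the file headers and coincide: slide 1 holds shControl 1 and 2, and slide 2 holds shControl 3 and the 3 shARID1A arrays.

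The log2 of the processed intensity was averaged over the spots of a probe, without outlier spots and control spots, and each array's 75th percentile was subtracted. Probes were kept if well above background on at least 3 of the 6 arrays. No probe was saturated. Probes were named through their Entrez gene or accession with a RefSeq gene table (assembly GRCh38.p14, used for names only, while coordinates are those of the files in hg19). A current gene symbol was found for 35793 of 58201 probes, and 22408 were left unnamed. A gene with several kept probes was represented by the probe of highest mean signal, and for 123 of 1976 changed genes with several kept probes another probe changed in the opposite direction. Signal over background limits what could be tested: of 23995 genes on the array, 16820 were kept.

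Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). Tables were handled with data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The 27 gene lists and all choices below were fixed before the data were examined, unless named otherwise. Lists were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 27 lists. At this preset correlation the p-value of a list rests mainly on the spread between genes, not on that between arrays. Bootstrap intervals over members do so too. A list's count of changed members was also adjusted over the list alone. With camera at an estimated correlation no list passed, over all arrays or with slide as a block (adjusted p = 0.898 for the G2/M list with slide as a block). The method fry, which tests whether a list's genes move one way without comparing them with other genes, called 11 lists. Where a gene was not well above background on any array of a group, its fold is a lower bound. It is the mean of the brighter group against the mean, per array, of the higher of the gene's own signal and the lowest signal of any probe well above background. Of the 7 lists called, the inflammatory one holds 1 such gene, and its median is 0.70 with or without the bound.

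The genes named are ARID1A and the 12 with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05. These 24 also had to have all 3 shARID1A arrays beyond all 3 shControl arrays, to be well above background on all 3 arrays of the higher group, not to be saturated on every array of a group, and to have a gene symbol that is no placeholder. From each list up to 4 members with the smallest adjusted p were named, or any tested member where fewer than 4 passed, and any member of the lists of SWI/SNF subunits and of genes tied to ARID1A loss. The single ARID1A value also had an exact permutation test.

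The fit was tested on simulated data for shARID1A against shControl, with 16820 genes at the measured levels and 50 genes changed at each size. It recovered 10% of genes changed by 0.5 on the log2 scale, 66% at 1, 76% at 1.5 and 98% at 2, which makes 125 of its 134 calls. Of the others, 3 were members of a simulated list shifted by a smaller amount and 6 were false. The simulated noise was independent between genes and arrays, without a slide difference, and far fewer genes changed than the 6355 called below. These rates therefore do not carry over to the real arrays. The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, median centring, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, an intensity trend with robust variance, array weights, the replicate number as a block, slide as a block, the deposited log2 values, and leaving out each array in turn. Chosen after seeing the data were slide as a random block, the comparison within slide 2, a 75th percentile over probes detected on all arrays, and a test of each kept probe on its own.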

Results

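Gene expression was measured on 6 one-colour Agilent arrays in KYSE-410, an established line of oesophageal squamous cell carcinoma cells. Cells of 3 arrays (shControl 1 to 3) carried a non-targeting short hairpin RNA, and cells of the other 3 (shARID1A 1 to 3) carried a hairpin against ARID1A, which encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. Both populations had been selected with puromycin. Between 46.8% and 53.2% of the 58201 non-control probes of an array were well above background, and 16820 genes were tested. shControl 1 and 2 lay on slide 1, whereas shControl 3 and all 3 shARID1A arrays lay on slide 2. The number of arrays limits the precision of every value below. Levels are log2 signal minus the array's 75th percentile, differences are shARID1A minus shControl, and errors of differences are standard errors with 3 arrays per group unless stated otherwise.

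The comparison asks which transcripts differ once ARID1A is depleted. ARID1A itself fell by 2.44 ± 0.15 on the log2 scale, which leaves 18.4% of the shControl level (limma adjusted p = 0.000369). Its level was 1.58, 1.76 and 1.40 on the shControl arrays and −0.92, −1.05 and −0.61 on the shARID1A arrays. All 3 shARID1A arrays lay below all 3 shControl arrays, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 arrays allow. The value rests on a single probe on chromosome 1, from 27107178 to 27107237 (hg19, per the file headers). With slide as a block, ARID1A fell by 2.26 ± 0.19 (adjusted p = 0.00539).

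ARID1A depletion was accompanied by a change in 6355 genes (adjusted p under 0.05), of which 3017 rose and 3338 fell. No other hairpin against ARID1A is described, so effects of ARID1A depletion and other effects of the hairpin cannot be told apart. A change of at least 2-fold was found for 1164 genes, 543 higher and 621 lower in shARID1A cells, and of at least 4-fold for 89 higher and 81 lower genes. Among the changed genes were 5455 protein-coding genes and 647 long non-coding RNAs. All 3 arrays of one group lay beyond all 3 of the other for 9141 genes (54.4%), against 10% for a single gene on exchangeable arrays. Genes share the same arrays and the groups differ in slide, so this share is no test of the hairpin. With slide as a block, 3455 genes passed (1883 higher, 1572 lower), of which 846 changed at least 2-fold, and 3207 of the 3455 were also called over all arrays. That fit takes the difference between groups from slide 2 alone, so its differences equal those of the 3 shARID1A arrays against shControl 3. Within slide 2, with a single control array assumed to vary like the others, 1969 genes passed (1053 higher, 916 lower), 769 of them at least 2-fold. Of the 1164 genes with a 2-fold change, 803 were still called within slide 2, a comparison that shares 4 of the 6 arrays. Leaving out single arrays moved these counts. Without shControl 1, 4039 genes changed (1948 higher, 2091 lower), without shControl 2, 3966 (1858 higher, 2108 lower), and without shARID1A 1, 3765 (1709 higher, 2056 lower). Without shARID1A 2, 1959 genes rose. Without shControl 3, 4555 genes rose, and 2146 changed at least 2-fold, 1414 of them higher. In that setting, here and below, the groups coincide with the slides, so it cannot tell the hairpin from slide. Centring each array on its median left 4536 genes, of which 32.4% rose, against 47.5% of the 6355. The median difference over all genes was 0.05 with the 75th percentile and −0.12 with median centring, so the balance of rises and falls is relative to the scaling.

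**Figure D1:**
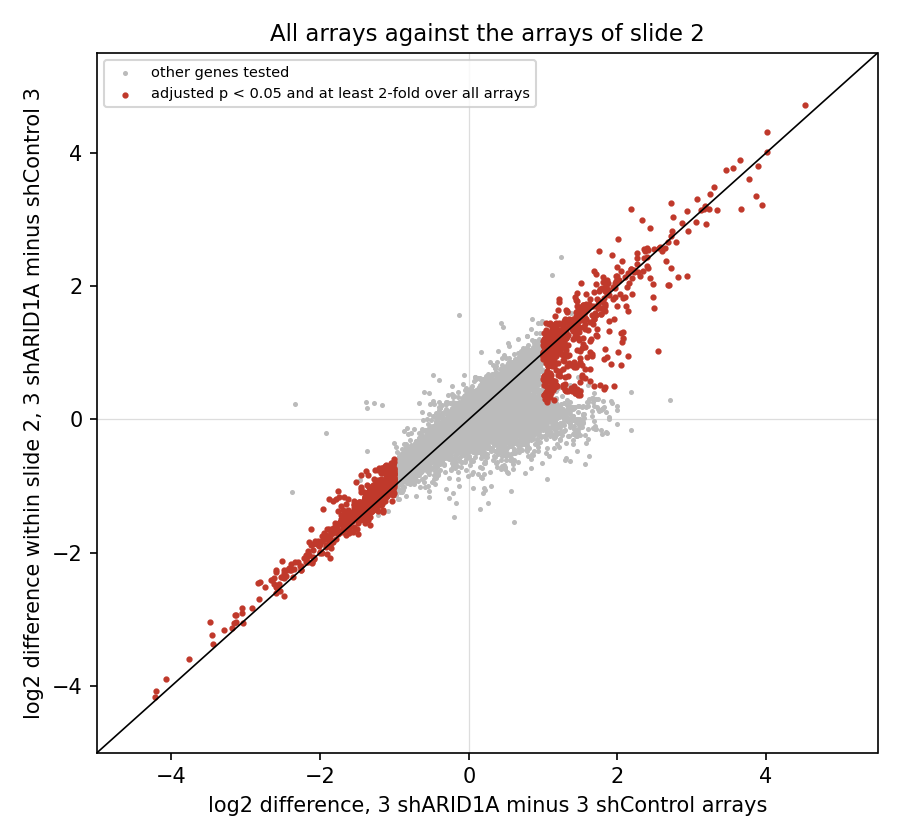
Log2 difference of each of the 16820 genes over all arrays (horizontal axis, 3 shARID1A minus 3 shControl arrays) against that within slide 2 (vertical axis, 3 shARID1A arrays minus shControl 3), with the line of equal values. The 1164 genes that changed at least 2-fold over all arrays are in red, and 4 of the 6 arrays enter both axes.

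The largest rise was that of NFE2, a transcription factor known from blood cells, at 23.1-fold (4.53 ± 0.14, adjusted p = 0.000108), and FST, which encodes the activin-binding protein follistatin, rose 16.2-fold (4.02 ± 0.21, adjusted p = 0.000255). CEACAM5, the carcinoembryonic antigen, rose 16.1-fold, and the proteoglycan gene CSPG4 15.4-fold. PRR15L rose 14.9-fold and KLHDC7B 13.6-fold. CRCT1, a gene of the epidermal differentiation complex, rose 12.7-fold, SPRR2A, a cornified envelope precursor, 10.1-fold, and the glycosyltransferase gene MGAT3 9.83-fold. PSG5, TM4SF18 and the neutrophil chemokine gene CXCL8 were not well above background on any shControl array, and were at least 4.13-fold, 2.57-fold and 2.48-fold higher in shARID1A cells (adjusted p = 0.000476, 0.000192 and 0.000717). CSPG4 and CRCT1 were well above background on 1 of the 3 shControl arrays, and SPRR2A on 2, so their folds rest partly on signal near background. The log2 difference of CSPG4 was 3.22 and that of CRCT1 3.16 with slide as a block, against 3.94 and 3.66 over all arrays. Sizes also depended on the probe, as other probes of SPRR2A and KLHDC7B differed by 1.54 and 2.84, against 3.34 and 3.77.

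ELMOD1 and AMPH had the largest falls. ELMOD1 fell 18.7-fold and AMPH, which encodes the endocytic protein amphiphysin, 18.4-fold (−4.20 ± 0.33, adjusted p = 0.000676), each with 2 of 3 shARID1A arrays well above background. ATP6V0A4, a subunit of the vacuolar proton pump, fell 13.6-fold and LYPD1 10.8-fold. The cytochrome P450 gene CYP2B6 fell 9.11-fold, although another of its probes differed by 0.29. PLAT, tissue plasminogen activator, fell 8.92-fold, and STRA6, the cellular receptor for retinol-binding protein, fell 8.74-fold (−3.13 ± 0.08, adjusted p = 9.4e-05), with another probe at −1.80. Not well above background on any shARID1A array were SKIDA1, SEMA5B, TNFRSF11B (osteoprotegerin), the transcription factor gene EGR4 and the calcium channel gene CACNA1D. These were at least 8.15-fold, 6.35-fold, 3.81-fold, 3.49-fold and 2.17-fold lower (adjusted p = 0.000369, 0.000225, 0.000342, 0.000108 and 0.000192). All 24 of these genes were also called with slide as a block and within slide 2.

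**Figure D2:**
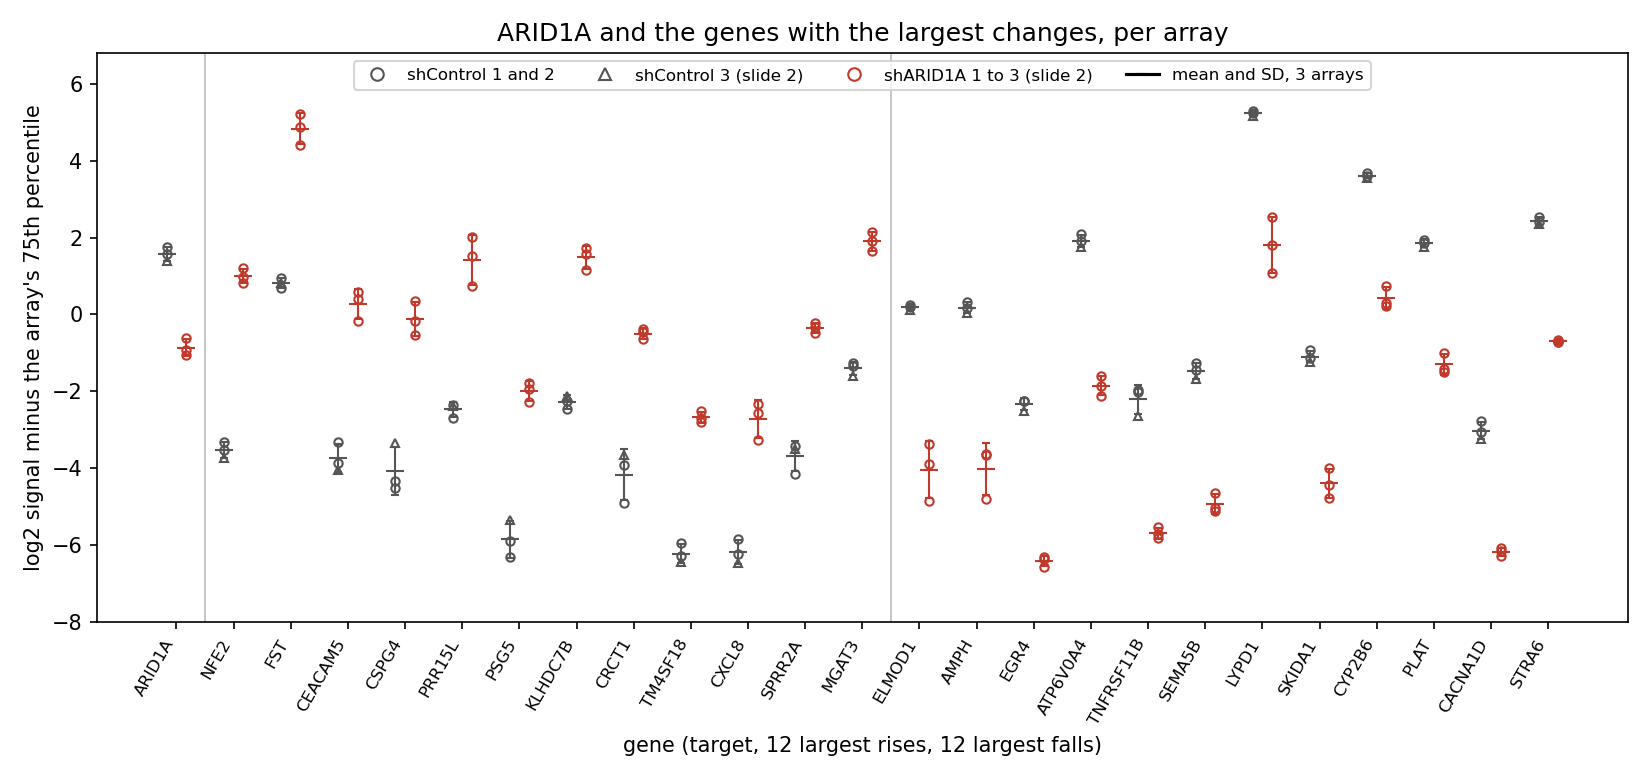
Level (log2 signal minus the array's 75th percentile) of ARID1A, the 12 genes of the largest rises and the 12 of the largest falls on each of the 6 arrays, with shControl in grey (triangle, shControl 3), shARID1A in red, and the mean and SD of 3 arrays as bars. ARID1A lies between 1.40 and 1.76 on the shControl arrays and between −1.05 and −0.61 on the shARID1A arrays, and for 8 of the 24 leading genes the lower group is not well above background and shows only a bound.

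The cornified envelope genes SPRR3 and SPRR2A rose, as did CEACAM6 and MUC1, markers of simple epithelium. Of 33 tested genes of suprabasal squamous differentiation, 14 rose and 4 fell (15 and 5 adjusted over the list alone). SPRR3 rose 8.30-fold (3.05 ± 0.11, adjusted p = 0.000126), SPRR2A 10.1-fold and SPRR1B 2.70-fold, while the keratin gene KRT80 fell 2.15-fold. Of 18 tested genes of simple and glandular epithelium, 6 rose and none fell (6 and 0 adjusted over the list alone, 10 and 1 without shControl 3). CEACAM5, CEACAM6 (6.39-fold), the membrane mucin gene MUC1 (7.65-fold) and the trefoil factor gene TFF1 (2.43-fold) were among the 6, with another probe of MUC1 at 1.35 against 2.94. Of 26 genes of desmosomes, adherens and tight junctions, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with CLDN1 at 1.05 ± 0.08, CLDN7 at 0.94 ± 0.09, NECTIN1 at 0.77 ± 0.10 and CLDN4 at 0.65 ± 0.09. The median of the list of simple epithelium was 0.30 (camera adjusted p = 0.00971, and adjusted p = 0.814 with an estimated correlation) and that of the junction genes 0.30 (camera adjusted p = 0.0197, and adjusted p = 0.814 with an estimated correlation). The squamous list did not pass (median 0.41, camera adjusted p = 0.0737), but passed without shARID1A 2 (adjusted p = 0.0245), with median centring (0.00206), without a filter on dim probes (0.0438), with array weights (0.0462) and with fry (0.00654). Its median was 0.22 with slide as a block (adjusted p = 0.104), with 10 genes rising and 4 falling. With slide as a block the median of the simple epithelium list was 0.26 and the call ended (adjusted p = 0.0719, and 0.0597 within slide 2), 4 of its genes still rising. The junction genes had a median of 0.33 with slide as a block (adjusted p = 0.00615, and 0.00684 within slide 2) with 9 rising, and the list's call ended without shControl 3 (adjusted p = 0.0775) at a median of 0.30, with 15 genes rising and 2 falling as before. Median centring lowered the medians of the simple epithelium and junction lists to 0.13 and 0.13, and both passed (adjusted p = 0.000574 and 0.047).

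Basal and mesenchymal genes moved in either direction. Of 21 tested basal squamous genes, 5 rose and 7 fell (8 and 9 adjusted over the list alone). CD44, a hyaluronan receptor, fell by 2.11 ± 0.17 and the anchoring fibril collagen COL7A1 by 1.97 ± 0.23, while the hemidesmosomal collagen COL17A1 rose by 0.84 ± 0.10 and the basal keratin KRT14 by 0.75 ± 0.09. Another probe of CD44 differed by 0.169 and another of KRT14 by −0.336. The list's median was 0.05, its mean −0.20 and its test pointed down without passing (camera adjusted p = 0.891). In the fit with slide as a block 5 rose and 3 fell, with a median of 0.24. Of 23 tested mesenchymal genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.328). When slide was a block, 4 rose and 4 fell. N-cadherin (CDH2) fell by 1.89 ± 0.25, COL5A1 by 1.37 ± 0.12 and the collagen cross-linking enzyme gene LOXL2 by 1.39 ± 0.20. The calls of CDH2 and LOXL2 ended within slide 2 (adjusted p = 0.0613 and 0.0771).

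CXCL1, CXCL2 and IL1B rose, and the list of inflammatory genes shifted upwards at the preset correlation. Of 26 tested NF-kB targets and inflammatory cytokines, 15 rose and 4 fell, counts that were equal when adjusted over the list alone. The neutrophil chemokine genes CXCL1 and CXCL2 rose 3.33-fold (1.74 ± 0.09, adjusted p = 0.000225) and 3.09-fold (1.63 ± 0.11, adjusted p = 0.000451), and interleukin 1 beta (IL1B) rose 4.68-fold (2.23 ± 0.19, adjusted p = 0.000837). The list's median was 0.70 (camera adjusted p = 0.00971, and adjusted p = 0.814 with an estimated correlation), and 0.60 with slide as a block (adjusted p = 0.00615, and 0.00386 within slide 2), where 12 genes rose and 3 fell. With median centring it was 0.53 (adjusted p = 0.000268). Of 37 interferon-stimulated genes, 11 rose and 6 fell (12 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.333). In the fit with slide as a block 10 rose and 1 fell, with a median of 0.21 against 0.13 over all arrays. OASL rose 3.22-fold, IFITM1 2.55-fold and IFIT2 2.43-fold, while IFI44L fell by 0.87 ± 0.09.

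Most G2/M and mitosis genes rose, while among G1/S and replication genes more fell than rose. Of 35 tested G2/M genes, 26 rose and none fell (29 and 0 adjusted over the list alone), with a median of 0.40 (1.32-fold). The mitotic kinase gene PLK1 rose by 0.89 ± 0.08, the centromeric histone gene CENPA by 0.71 ± 0.08, the spindle checkpoint gene BUB1B by 0.64 ± 0.08 and cyclin B1 (CCNB1) by 0.61 ± 0.08. Of 36 tested G1/S and replication genes, 4 rose and 15 fell, counts that were equal when adjusted over the list alone, with a median of −0.20. The DNA polymerase gene POLA1 fell by 0.84 ± 0.09, GINS3 by 0.71 ± 0.08 and the flap endonuclease gene FEN1 by 0.60 ± 0.07, while GINS1 rose by 1.54 ± 0.12. The G2/M list passed (camera adjusted p = 5.1e-07, and adjusted p = 0.814 with an estimated correlation), as did the G1/S list (camera adjusted p = 0.0359, and adjusted p = 0.814 with an estimated correlation). With slide as a block the G2/M median was 0.51 with 25 genes rising (camera adjusted p = 4.0e-10), and within slide 2, 9 genes rose (camera adjusted p = 1.3e-09). With median centring it was 0.23 (adjusted p = 0.000595). The G1/S call ended with slide as a block (median −0.15, adjusted p = 0.1, and 0.0993 within slide 2), without shControl 1 (median −0.15, adjusted p = 0.0681) and without shARID1A 3 (median −0.18, adjusted p = 0.0826). It also ended at an unchanged median on genes well above background on all arrays (adjusted p = 0.0541) and with fry (adjusted p = 0.0556), and at a larger one with median centring (−0.37, adjusted p = 0.0689).

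SMAD7, FSTL3 and ITGAV fell, and the list of TGF-beta response genes shifted downwards at the preset correlation. Of 24 tested targets, 1 rose and 13 fell (1 and 14 adjusted over the list alone), with a median of −0.48 (95% bootstrap interval over members −0.761 to 0.0108). The inhibitory SMAD gene SMAD7 fell by 0.92 ± 0.10, FSTL3, a follistatin-like binding protein, by 0.94 ± 0.11, integrin alpha V (ITGAV) by 0.89 ± 0.10 and the cyclin-dependent kinase inhibitor CDKN2B by 0.54 ± 0.06. The list passed (camera adjusted p = 0.00971, and adjusted p = 0.814 with an estimated correlation), and with slide as a block its median was −0.37 (adjusted p = 0.00891, and 0.0108 within slide 2) with 7 genes falling. With median centring it was −0.65 (adjusted p = 0.00257). Of 29 immediate-early genes, 9 rose and 9 fell (10 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.459), except with fry (0.0419). The MAP kinase phosphatase gene DUSP5 rose 4.39-fold, PHLDA1 3.24-fold and MAFF 2.48-fold, while FOSB, an AP-1 subunit, fell by 1.26 ± 0.08.

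Of 30 tested genes of oxidative phosphorylation, 11 rose and none fell (14 and 0 adjusted over the list alone), with a median of 0.21. The complex III gene UQCRC2 rose by 0.72 ± 0.09, the ATP synthase gene ATP5F1B by 0.52 ± 0.08, succinate dehydrogenase subunit SDHB by 0.47 ± 0.08 and cytochrome c1 (CYC1) by 0.42 ± 0.07. The list passed (camera adjusted p = 0.00854, and adjusted p = 0.814 with an estimated correlation), also with slide as a block (median 0.23, adjusted p = 0.00135, and 0.00314 within slide 2, 5 genes rising). Its call ended with quantile normalization (median 0.10, adjusted p = 0.0914), with normexp background correction and quantile normalization together (median 0.09, adjusted p = 0.116), with median centring (adjusted p = 0.188) and in the deposited values (median 0.10, adjusted p = 0.0915). The list of 30 reference genes had a median of 0.23 over the same arrays, and with median centring the medians of the oxidative phosphorylation and reference lists were 0.04 and 0.06. Of 29 hypoxia-inducible and glycolytic genes, 15 rose and 6 fell (16 and 6 adjusted over the list alone). Hexokinase 2 (HK2) rose 3.49-fold, VEGFA 1.87-fold and pyruvate dehydrogenase kinase 1 (PDK1) 1.59-fold, while the glycolytic regulator PFKFB3 fell by 1.03 ± 0.07. This list did not pass over all arrays (median 0.33, camera adjusted p = 0.0661), and passed with slide as a block (median 0.34, adjusted p = 0.0312, and 0.0356 within slide 2) and without shARID1A 2 (adjusted p = 0.0418). It also passed without a filter on dim probes (0.0355), on genes well above background on all arrays (0.0487), with the mean of a gene's probes (0.0229) and with fry (0.0107).

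Transcripts of a few other SWI/SNF subunits changed. Their list holds subunits of the BAF, PBAF and ncBAF forms, so a listed subunit need not share a complex with ARID1A. Of 26 tested SWI/SNF subunits, 2 rose and 7 fell, counts that were equal when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.185). In the fit with slide as a block 0 subunits rose and 4 fell, and within slide 2, 0 rose and 1 fell. SS18L1 fell by 0.66 ± 0.08 (adjusted p = 0.00221), BICRAL by 0.58 ± 0.08 (adjusted p = 0.00362) and the core subunit SMARCC2 by 0.52 ± 0.08 (adjusted p = 0.00408). ARID1B, the paralogue of ARID1A, differed by 0.25 ± 0.08 (adjusted p = 0.0544), with other probes from −0.23 to 0.32. Of 15 tested genes tied to ARID1A loss in other published systems, 1 rose and 5 fell (3 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.461). ANXA1 rose by 0.61 ± 0.06, while the cystine transporter gene SLC7A11 fell by 0.67 ± 0.08 and the cell cycle inhibitor CDKN1A fell 1.99-fold. Among the genes named here, the calls of TFF1, CLDN4, ATP5F1B, SDHB, CYC1, BICRAL, SMARCC2, CDKN1A and ESAM also ended within slide 2 (adjusted p = 0.0501 to 0.097), and all of them were called with slide as a block.

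**Figure D3:**
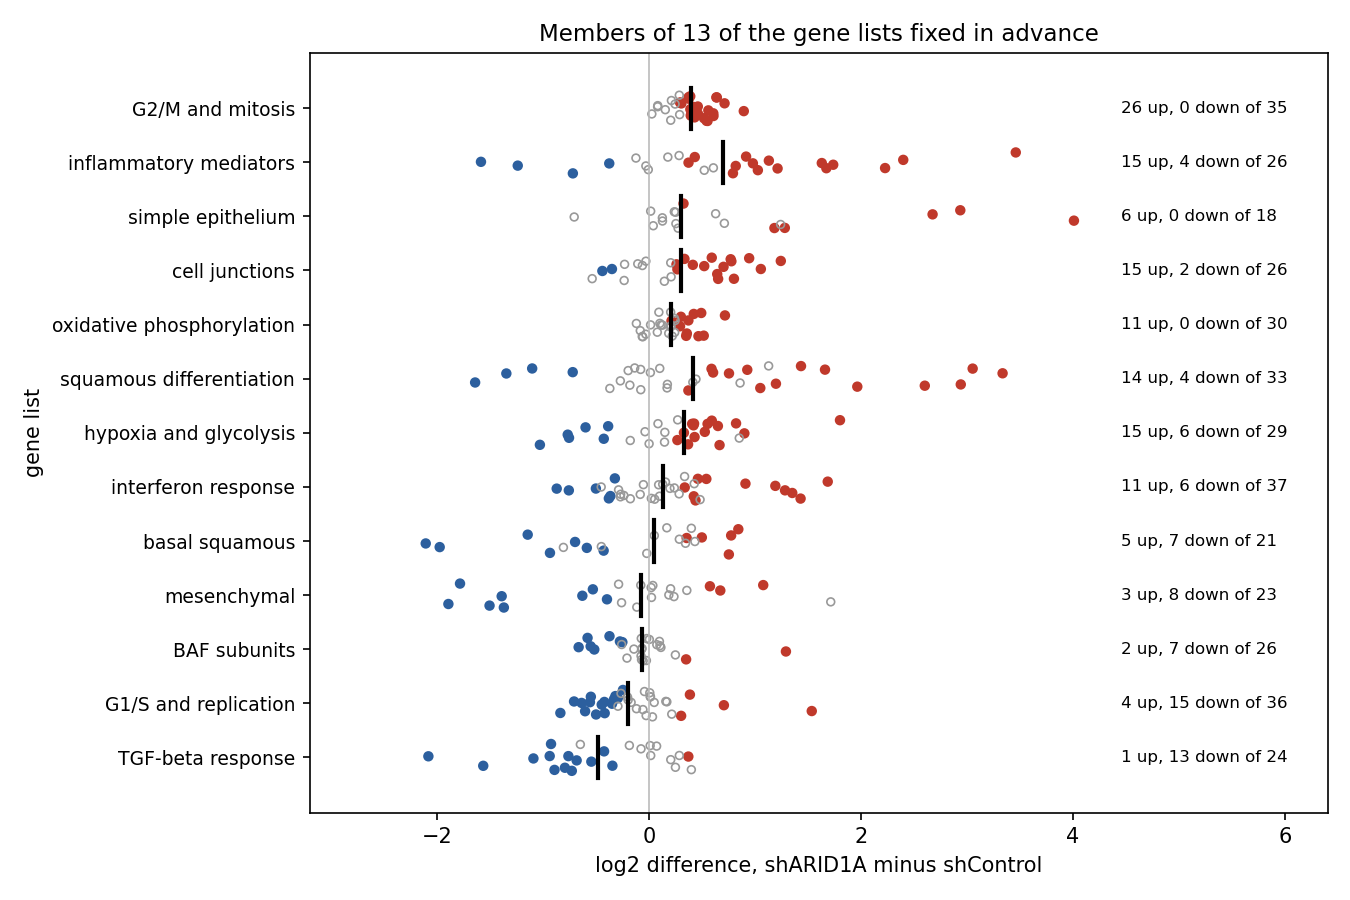
Log2 difference (shARID1A minus shControl, horizontal axis) of each tested member of 13 gene lists, with rises in red, falls in blue, members past no threshold as open circles and the list's median as a black bar. The median is 0.40 for G2/M genes and −0.48 for TGF-beta response genes, and 3 of the members are plotted at a fitted difference although their lower group was not well above background.

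Markers of other cell types and common reference genes were followed as checks. Of the fibroblast markers 1 rose and 1 fell of 10 tested (1 and 1 adjusted over the list alone, 3 and 1 without shControl 3), with LUM at 0.65 ± 0.09. Of the leukocyte markers 1 rose and 2 fell of 13 tested (1 and 2 adjusted over the list alone), with LCP1, an actin-bundling protein gene, at 1.38 ± 0.09. Of the endothelial markers 3 rose and 1 fell of 5 tested (3 and 1 adjusted over the list alone), with ESAM at 0.86 ± 0.12 and VWF at −1.15 ± 0.11, another probe of which differed by 0.579. None of these lists passed (camera adjusted p = 0.323, 0.169 and 0.333), and the leukocyte list passed without shControl 3 (adjusted p = 0.0201, 10 of its 13 genes rising), without a filter on dim probes (0.0438) and with array weights (0.0351). The fibroblast list passed with fry (0.0419). The median of the 28 pooled markers was 0.55 over all arrays and 0.12 within slide 2. Of 30 reference genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, 15 and 2 without shControl 3). Their median was 0.23 over all arrays, 0.09 with slide as a block and 0.06 with median centring. The reference list did not pass (camera adjusted p = 0.0661), but passed without shARID1A 3 (adjusted p = 0.046), without a filter on dim probes (0.0237), on genes well above background on all arrays (0.0487), with array weights (0.0351) and with fry (0.0372).

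The arrays of a group correlated at 0.988 to 0.996 among shControl and 0.995 to 0.996 among shARID1A over the tested genes, and at 0.971 to 0.984 between the groups. shControl 3 stood apart from the other control arrays, towards the shARID1A arrays. It correlated at 0.983 to 0.984 with each shARID1A array, against 0.971 to 0.974 for shControl 1 and 2, and on the first principal component (72.5% of the variance) it lay at −0.137, between shControl 1 and 2 (−0.505 and −0.522) and the shARID1A arrays (0.37 to 0.414). Its level differed at least 2-fold from the mean of shControl 1 and 2 for 1046 of the 16820 genes (6.22%), while shControl 1 and 2 differed so for 254 genes. On 284 probes printed in replicate spots, the median SD over arrays was 0.154 among shControl and 0.0829 among shARID1A, and over all tested genes it was 0.125 and 0.107.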

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

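The tests of slide for the G2/M genes and the other cell types, of the G1/S genes and of shARID1A RNA in shControl 3 were chosen after the results were seen.

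Probes without a current gene symbol, which no comparison above uses, held signal that differed between the groups. Of 6870 such probes kept, 1422 (20.7%) changed, 687 higher and 735 lower in shARID1A cells, and 498 of these changed at least 2-fold. The 8 spike-in transcripts detected on all arrays were added during labelling and do not come from the cells. Their mean log2 level was 4.10 ± 0.08 (SD, n = 3) in shARID1A and 4.20 ± 0.14 (SD, n = 3) in shControl. The difference was −0.0941, with an exact two-sided permutation p of 0.4. Single spike-ins differed by −0.286 to 0.3066, so this mean pools shifts in both directions. Every spike-in of shControl 3 lay nearer to the shARID1A mean than to shControl 1 or 2. These shifts thus went with the slides rather than with the groups.

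The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For genes changed, 1 of the 10 splits reached the count of 6355, the labelled one, and the highest other count was 0. For genes changed at least 2-fold, 1 split reached 1164, and the highest other was 0. For gene lists shifted, 4 splits, the labelled one included, reached 7, and the highest other was 9. Splits that mix the groups thus gave as many lists, so the count of 7 does not set the labelled split apart. For chromosomes shifted, the count was 0 in all 10.

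The G2/M list had a smaller camera p at the preset correlation than any other list (adjusted p = 5.1e-07), and did not pass with an estimated correlation (adjusted p = 0.814). Its median with slide as a block, where the difference rests on shControl 3, was 0.5103 (95% bootstrap interval over members 0.478 to 0.577), against 0.397 over all arrays, which argues against slide as the whole source. Of 10000 random lists matched on brightness, 0% reached the median, which argues against brightness. A larger share of cycling cells would raise G1/S genes about as much, and their median was −0.1999 over all arrays (95% bootstrap interval −0.324 to −0.0178) and −0.1548 within slide 2 (−0.2393 to 0.01155), which argues against it. An effect of ARID1A depletion on the cycle stays open, and no test here decides it.

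The 28 pooled markers of fibroblasts, leukocytes and endothelium had a median difference of 0.55 over all arrays. It was 0.1224 within slide 2 (95% bootstrap interval −0.214 to 0.252), so slide could account for most of it. Of random lists matched on brightness, 0.35% reached the median, which argues against brightness alone, with these markers at a median percentile of 19.8 in level. With slide as a block at most 40% of a list's tested markers rose, 2 of 5 endothelial genes, whereas without shControl 3, 10 of 13 leukocyte and 4 of 5 endothelial markers rose. The rises without shControl 3 compare slide 1 with slide 2, so they cannot tell other cells from slide. The counts with slide as a block met the bound set beforehand for excluding cells of another type. That bound rests on shControl 3 alone, so such cells stay open.

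shControl 3 differed from shControl 1 and 2 mainly among dim genes, and lay towards the shARID1A arrays: of the dimmest of 4 equal groups of genes 20.3% were at least 2-fold apart and of the brightest 0.69%, a ratio of 29.5. The mean of the spike-ins lay at −0.242 in shControl 3 relative to shControl 1 and 2. The range among the shARID1A arrays was smaller, at 0.149. Both values are relative to each array's 75th percentile, which probes for the cells' transcripts set. As intensity, that percentile was 360 in shControl 3, against 286.5 and 288 in shControl 1 and 2. The mean therefore cannot tell a shift of the spike-ins from a shift of the percentile. It also pools spike-ins that moved both ways, which a shift of the percentile alone cannot give. E1A_r60_n9 stood at 8.083 in shControl 3 against 7.734 and 7.637 in shControl 1 and 2, and E1A_r60_a107 at −3.167 against −2.645 and −2.591. On the shARID1A arrays of the same slide, E1A_r60_n9 stood at 8.186, 8.093 and 8.095 and E1A_r60_a107 at −2.939, −3.127 and −3.195. The spike-ins do not come from the cells. A difference between slides or hybridisations could give their opposite shifts, and could also give the ratio. A share of shARID1A RNA in shControl 3, fitted at 25.1% from the brightest genes, would place 178 genes higher in shARID1A cells at a median of 0.464 above shControl 1 and 2. They lay at 0.0945 (95% bootstrap interval 0.011 to 0.248), which argues against that share but not against a smaller one, and ARID1A itself lay at −0.188 relative to the lower of the other control arrays, where that share would give −0.247. A difference in the culture behind shControl 3 was not tested.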

How the results depend on the processing

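ARID1A fell past the threshold under every alternative run, between −2.61 with median centring and −2.05 with normexp and quantile normalization together, and between −2.57 and −2.35 with 1 array left out. The 24 leading genes were called in each of the 20 settings in which they were tested, with adjusted p up to 0.0353. For the 158 named genes other than ARID1A, repeats under these settings ended a call in 174 cases, added one in 36 and left it as it was in 2931, and 24 of the losses came with median centring, 18 with slide as a block and 42 within slide 2, where a single control array is left. MSH6 alone reversed, to 0.15 with the mean of its probes. Normexp (offset 50) with quantile normalization lowered the genes changed at least 2-fold to 477 (201 higher, 276 lower), and median centring lowered the genes that rose to 1468. Array weights raised the counts to 11550 (6148 higher, 5402 lower), of which 2229 changed at least 2-fold and 1435 rose so. These 2-fold rises were close in number to the 1414 without shControl 3. Whether the weights set that array aside was not examined, so this setting may also follow the slides. Slide as a block left 3455 (1883 higher, 1572 lower), and within slide 2 left 1969 (1053 higher, 916 lower), with 769 changed at least 2-fold and 363 of these lower. Testing each kept probe gave 2030 at least 2-fold, since more features are tested. Gene lists shifted numbered 0 with an estimated correlation, 11 with fry and 11 without a filter on dim probes. With 1 array left out, the count of changed genes ranged from 3765 to 8744, of rises from 1709 to 4555, of falls from 2056 to 4189, of changes at least 2-fold from 997 to 2146, of such rises from 455 to 1414, of such falls from 532 to 732, and of lists from 6 to 9. The highest counts of genes were those without shControl 3, where the groups coincide with the slides. The highest count of lists was that without shARID1A 2. Chromosomes shifted numbered 0 in every setting run. Apart from the smaller numbers of samples or of features tested, the cause was not tested. Arrays of the same replicate number deviated from their group means with correlations of −0.037, 0.0162 and −0.0384, so no pairing showed. Deviations among shControl include the difference between slides, so this check cannot exclude a pairing. With the replicate number as a block 4686 genes passed, 2193 higher and 2493 lower. Signal near background limits the size that can be given to large changes, as 8 of the 24 leading genes have only a bound.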

Other observations

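The tests of gene families and the test of copy number by chromosome were chosen after the results were seen. Of 25 tested cholesterol genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.461), with INSIG1 rising by 0.84 ± 0.11. Of 30 genes of the unfolded protein and integrated stress responses, 12 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.333). The serine and one-carbon enzymes PSAT1 and SHMT2 rose by 0.92 ± 0.11 and 1.05 ± 0.10 and TRIB3 by 0.92 ± 0.08, while the phosphatase subunit gene PPP1R15A fell by 0.52 ± 0.07. Of 27 p53 targets, 5 rose and 7 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.961). GDF15 rose 3.68-fold, while TP53INP1 fell by 1.23 ± 0.19 and XPC by 0.54 ± 0.07. The calls of PPP1R15A, TP53INP1, XPC and RAD51D ended within slide 2 (adjusted p up to 0.0733). In the fit with slide as a block, 10 stress response genes rose and 1 fell, and 5 p53 targets rose and 3 fell.

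Of 30 genes of homologous recombination and the DNA damage response, 1 rose and 5 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.109). The list passed without shControl 3 (median −0.21 against −0.16, adjusted p = 0.0328), where 1 rose and 13 fell. With slide as a block 0 rose and 2 fell. RAD51D fell by 0.61 ± 0.08, with other probes from −0.56 to 0.24. Of 29 NRF2 targets, 3 rose and 5 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.887), with EPHX1 falling by 1.07 ± 0.13. Of 21 YAP/TAZ targets, 3 rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.599), with IGFBP3 rising by 1.29 ± 0.19 and AJUBA falling by 0.73 ± 0.08. Of 15 WNT targets, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.322), with APCDD1 falling by 0.78 ± 0.07. Of 22 genes of antigen presentation, 3 rose and 1 fell (3 and 0 adjusted over the list alone, 9 and 2 without shControl 3). The list did not pass (camera adjusted p = 0.599), and the immunoproteasome gene PSMB10 rose by 0.52 ± 0.08.

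Among 372 families of at least 6 protein-coding genes that share a symbol stem, 8 passed camera over all arrays and 4 of these also with slide as a block, and 0 passed with an estimated correlation (adjusted p = 0.993). CEACAM genes had a median of 1.49 with 6 of 8 rising, SPRR genes 1.66 with 6 of 7 rising, and SERPINB genes 1.14 with 5 of 8 rising. PCDHB genes, a cluster of protocadherins, had a median of −0.54 with 9 of 13 falling. With slide as a block the call of 4 families ended. CXCL genes (6 of 9 rising) had a median of 1.21 over all arrays and 1.48 with slide as a block (adjusted p = 0.08), and intraflagellar transport genes (IFT, 9 of 18 falling) −0.41 and −0.35 (adjusted p = 0.0909). Olfactory receptor genes (OR, 11 of 54 rising and 4 falling) had a median of 0.82 over all arrays and −0.06 with slide as a block (adjusted p = 0.81), and ribosomal protein genes (RPL, 8 of 49 rising) 0.24 and 0.12 (adjusted p = 0.22).

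A copy number difference between the selected populations could move the genes of a chromosome together. With camera, 0 of 23 chromosomes passed over all arrays, with slide as a block or with an estimated correlation (smallest adjusted p = 0.933), and 0 had an unadjusted p under 0.05 with either correlation. The chromosome medians ran from 0.00429 on chromosome 6 to 0.16 on chromosome 21. The largest distance from the median of all genes was 0.113, below the 0.208 used as a bound, 0.5 times the log2 change from 3 copies to 4. This argues against a whole-chromosome difference, and smaller segments were not tested.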
